A study of Mus musculus with 9 samples.

How the data were processed

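RNA was measured in 9 libraries from micromass cultures, high-density drops of cells taken from mouse forelimbs at embryonic day 12 and grown in a medium that lets limb mesenchyme form cartilage. Per the labels' protocols, 3 cultures received the pan-caspase inhibitor Z-VAD-FMK (FMK), 3 received the pan-caspase inhibitor Q-VD-OPH (OPH) and 3 received the vehicle, DMSO, in parallel. The inhibitors were given at 100 µM for 6 days, with the medium changed every second day. The labels call the 3 cultures of each condition biological replicates and do not say whether equal numbers share a litter or a day. Libraries were made with a kit that reads the 3' ends of polyadenylated RNA, so a count stands for a transcript end and says nothing about splicing or the rest of the transcript.

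The authors' deposited table held raw counts per gene and library, which were whole numbers summing to 5659789 to 6867350 per library, and a summed count per group that equalled the sum of its 3 libraries for 3 of 3 groups. Per the file headers, the authors also deposited for each of 3 comparisons a DESeq2 mean signal over all libraries (counts divided by size factors), a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted p-value. Signs against the counts showed that each log2 fold change was the first group over the second. Per the submitters' processing notes, FastQC, MultiQC, cutadapt, STAR and DESeq2 were used with the mm10 genome, without versions. The counting program, its annotation, its use of strand and its treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes, such as Ifit3 and Ifit3b, the H2, Gbp, Oas and Mx families, and of overlapping or antisense genes may therefore have been split or dropped, and values of these genes are uncertain. The authors' mean signal was used for no result.

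The table listed 52550 genes and 99 spike-in rows with 1 count in all, which were left out. Of the gene identifiers, 52403 (99.7%) were found in GENCODE M21 (GRCm38, the same assembly as mm10), and 50566 of those (96.5%) had the same start, so positions and biotypes are given from that annotation. Several identifiers shared a symbol in 90 cases, and tests were made per identifier. All 9 library columns were matched to samples by their names. Those of DMSO 3 and OPH 3 equal the sample titles and the other 7 add a letter to them, for a reason not given in the sources used here. In all, 2 measurement columns, repeats of the authors' mean signal, were left unmapped. Pairs of libraries of one group differed by more than counting noise (chi-square per degree of freedom 6.05 to 15.5), so none were copies of each other. Separate preparation alone would give such a spread, and that the replicates are biological rests on the labels.

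Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (13255 genes, holding at least 99.7% of the counts of every library), libraries were scaled by TMM, and a robust quasi-likelihood model with 1 coefficient per group was fitted to all 9 libraries without a block. Each comparison used the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Adjusted p in the text is this value unless another tool is named. Values in CPM are edgeR's counts relative to the TMM-scaled library size, given as mean ± SD of 3 libraries, and log2 fold changes are given ± the standard error of the fit. The common dispersion was 0.0243, a biological coefficient of variation of 0.156. TMM factors were 1.02 to 1.03 with DMSO, 0.946 to 0.963 with FMK and 1.02 to 1.03 with OPH. Scaling by library size alone moved the median log2 fold change of all genes to -0.11 with FMK against DMSO and to 0.12 with OPH against FMK, so changes are relative to the TMM scaling. An exact permutation test of 3 libraries against 3 cannot give a two-sided p under 0.1, which is why single values were tested in the model across genes.

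The depth sets a floor. A gene with 0 counts in the 3 libraries of a group was taken to lie at or under 3 counts over the group, which is 0.147 to 0.166 CPM, and its fold is printed as a lower bound. Genes with 1 to 3 counts in a group are given as a ratio of counts with a 95% counting interval. Reads copied by PCR are not independent molecules where they are not told apart by molecular identifiers, so floors and counting intervals cover counting error only.

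Before the data were examined, the comparisons, the test, the alternatives, 28 gene lists and the rule for naming genes were fixed. The lists came from textbook knowledge: cartilage matrix, chondrogenic regulators, hypertrophic cartilage, osteoblast, matrix-degrading proteases and inhibitors, osteoarthritis-related mediators, interferon response, NF-kB targets and chemokines, caspases, apoptosis regulators, necroptosis and pyroptosis, p53 targets, integrated stress response and amino acid genes, endoplasmic reticulum chaperones, NRF2 and glutathione genes, lysosome and cathepsins, cholesterol synthesis, glycolysis and hypoxia, cell cycle, joint, tendon and perichondrium markers, skeletal muscle markers, endothelial markers, macrophage and osteoclast markers, ectoderm and keratinocyte markers, glial and melanocyte markers, adipocyte markers, mitochondrially encoded genes and erythroid markers. The 8 lists of markers cover other cell types a limb bud culture can hold. The erythroid list had 1 measured member and was not tested, so 27 lists were. The title of the series speaks of osteoarthritis, and the list of osteoarthritis-related mediators was set here independently of these libraries, with 20 of its 41 measured members also on other lists. Lists were tested with camera for counts (limma 3.58.1, two-sided, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 27 lists, and again with the correlation estimated from the data. Numbers of members that rose or fell are given over all genes tested and adjusted over the list alone, and with the replicate number as a block where that moved a number by more than 1.5 times and at least 2 genes. The adipocyte list held 1 member at 0 in FMK libraries, and its medians were the same with that member at its bound.

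Named genes were, for each comparison, the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, leaving out symbols of predicted genes, pseudogenes and mitochondrial genes. Cxcl11, annotated as a polymorphic pseudogene, passed this rule by its symbol. From every called list up to 4 members and from every other list up to 2 members with the smallest unadjusted p past the threshold were eligible, named in that order, and the text names fewer. Col2a1, Acan, Sox9, Col10a1, Mmp13, Runx2, Spp1, Casp8 and Casp9 were always named against DMSO. Results of some other genes named in advance or by the list rule are not reported here. They were tested like all others and count in the gene and list totals, but are left out of the counts of named genes under the alternatives, where some had changed direction. Ifnb1 outside the comparison of FMK with DMSO, the genes that moved in opposite directions with the inhibitors, and the genes and lists of the last part were chosen after their values were seen.

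Pairing by replicate number was checked before calls were compared. Over 10010 genes, deviations from the group means correlated at 0.197 to 0.469 in the 9 pairs of libraries with equal numbers and at -0.387 to 0.0246 in the 18 other pairs, so every equal-number pair passed 0.1 and the numbers were taken to pair the libraries. The pairing comes from the data, since the labels give only the numbers. Xist averaged 283 CPM in the libraries numbered 1, 135 in those numbered 2 and 124 in those numbered 3, and Ddx3y averaged 52.7, 101 and 94.6. The main fit was fixed in advance without a block, and a fit with the number as a block was an alternative. The 10% of genes whose libraries would not overlap by chance holds for unpaired libraries and ignores the pairing.

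Other alternatives were DESeq2 median-of-ratios (RLE) scaling, library size alone, no low-count filter, a stricter filter (5 CPM in at least 3 libraries), only the 2 groups compared in the fit, a minimum fold of 1.5, DESeq2 1.42.0, limma-voom, and each library left out in turn. The libraries numbered 1 and 2 alone, and the block together with the estimated correlation, were added after the data were seen. Tests were run on data simulated from these libraries' means. For FMK against DMSO, 77 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were recovered, with 14 of 13055 unchanged genes called. For OPH against DMSO, unchanged there, 0 of 13255 genes were called. A list raised 1.5-fold in another simulation was called with 0 of 26 others. This cannot gauge real libraries, where another split of OPH and DMSO called 15 lists.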

Results

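The data were gene counts of 9 libraries, 3 each from mouse limb micromass cultures kept for 6 days with the vehicle DMSO, with 100 µM FMK or with 100 µM OPH. Library totals were 5659789 to 6867350 counts, and 16588 to 17656 genes had at least 1 count in a library. The 10 most abundant genes held 9.54% to 12.9% of the counts, and genes of the mitochondrial genome held 1.65% to 2.90%. With DMSO the cultures held cartilage transcripts, among them Col2a1, the main collagen of cartilage, at 1333 ± 301 CPM (SD, n = 3). They also held transcripts of macrophages, such as Mrc1 at 133 ± 64.4 CPM, and of adipocytes, such as Lpl at 736 ± 363 CPM. The mean log2 CPM of the adipocyte list was 6.68 and 6.29 in DMSO libraries 1 and 2 and 4.0 in DMSO library 3. That of the skeletal muscle list was 3.03, 3.61 and 4.87. In the FMK and OPH groups too, library 3 had the lowest adipocyte level and the highest muscle level.

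The comparison of FMK with DMSO asked which transcripts change when caspases are inhibited in these cultures. FMK raised interferon-stimulated genes together, with 41 of 42 list members higher. It also raised inflammatory and osteoarthritis-related genes such as Mmp3, a matrix-degrading protease, from 0.458 ± 0.137 to 42.5 ± 15.9 CPM (SD, n = 3). Transcripts of macrophages almost vanished, and Tyrobp, a signalling adaptor of myeloid cells, fell from 118 ± 24.7 to 1.07 ± 0.408 CPM. Of the cartilage matrix genes 15 of 25 fell, among them Col2a1, at 424 ± 38.6 CPM against 1333 ± 301 with DMSO. As a list they were called with the preset correlation but not with an estimated one (adjusted p = 0.192). In all, 2722 of 13255 genes passed the threshold (20.5%). Of these 1381 rose and 1341 fell, 518 and 569 of them at least 2-fold.

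**Figure D1:**
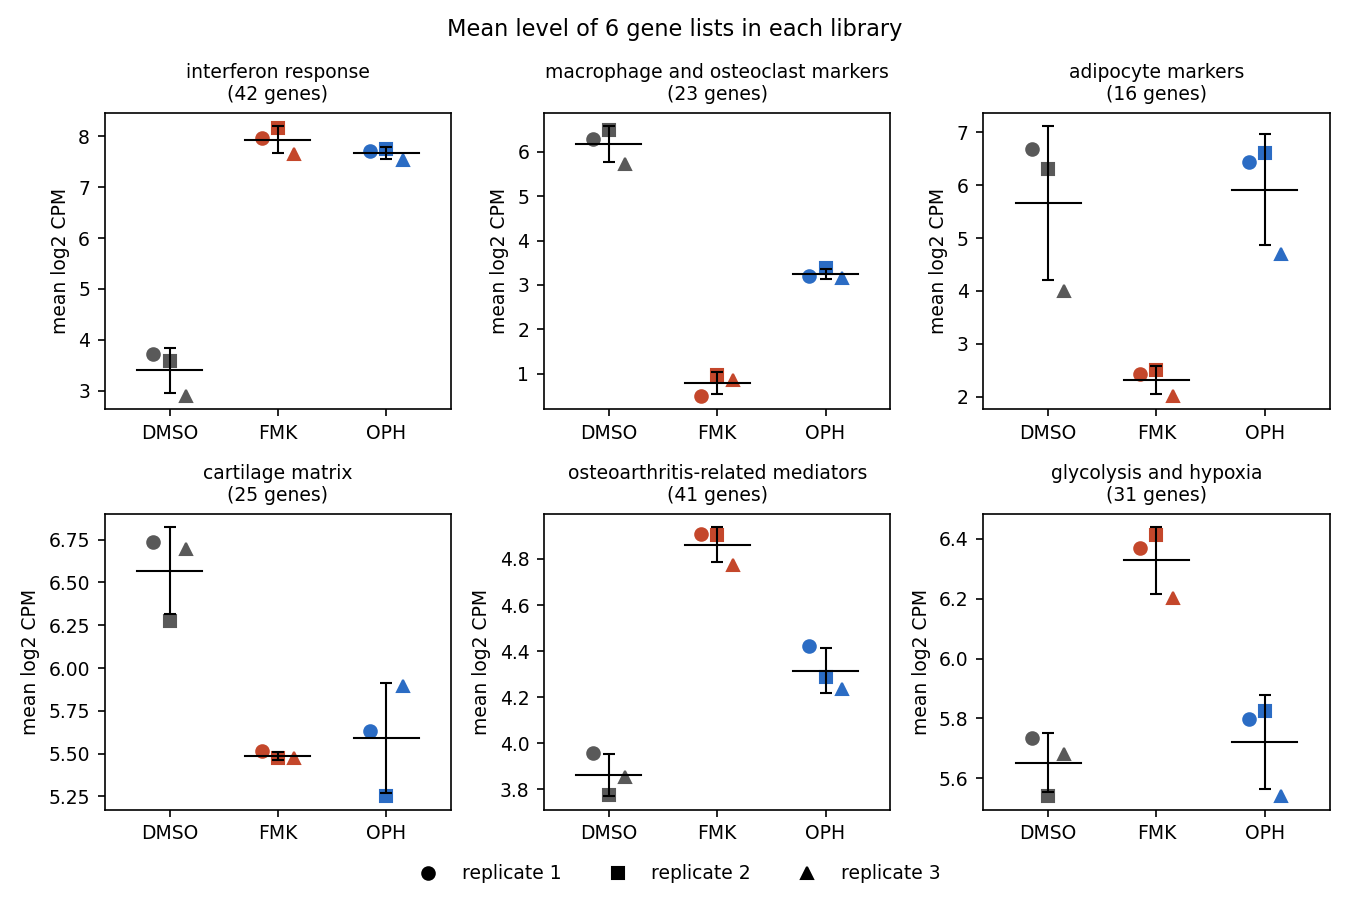
Mean log2 CPM of the measured members of 6 gene lists in each library, by group; symbols mark the replicate number, the horizontal line is the group mean and the bar its SD (n = 3). Interferon response levels were 2.90 to 3.72 with DMSO and 7.53 to 8.17 with the inhibitors, and macrophage and osteoclast levels were 5.72 to 6.49 with DMSO, 0.51 to 0.98 with FMK and 3.16 to 3.38 with OPH.

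The largest rises with FMK were those of interferon-related genes. Ifnb1, which encodes interferon beta (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774, minus strand), had 0 counts with DMSO and 10.4 ± 1.33 CPM with FMK. It was at least 68.6-fold higher (adjusted p = 4.25e-07). The chemokine gene Cxcl10 rose from 2.24 ± 1.49 to 752 ± 267 CPM (log2 fold change 8.37 ± 0.49, adjusted p = 4.49e-05). Ccl5, another chemokine gene, rose by 8.03 ± 0.33, Plac8 by 7.81 ± 0.39 and Mx1, an antiviral GTPase gene, by 7.33 ± 0.55 on the log2 scale. Cxcl11 had 2 counts with DMSO and 793 with FMK, a ratio of 429 (95% counting interval 119 to 3553). Its call (adjusted p = 0.00276) was lost in the libraries numbered 1 and 2 (adjusted p = 0.187). Of the interferon response list, 41 of 42 rose and 0 fell (41 and 1 adjusted over the list alone). Across the list the median log2 fold change was 4.43 (camera adjusted p = 3.37e-187). Gbp3, a guanylate-binding protein gene, rose by 4.98 ± 0.15, the RNA sensor gene Ddx58 by 2.66 ± 0.10 and the transcription factor gene Irf9 by 2.09 ± 0.10.

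Inflammatory genes moved in the same direction. Of the NF-kB targets and chemokines, 21 of 25 rose and 0 fell (21 and 0 adjusted over the list alone). The list's median log2 fold change was 2.07 (camera adjusted p = 6.70e-31). Nfkbia, the feedback inhibitor of NF-kB, rose by 1.46 ± 0.10, the neutrophil chemokine gene Cxcl1 by 4.38 ± 0.34 and the acute-phase gene Saa3 by 3.71 ± 0.30. Of the osteoarthritis-related mediators, 22 of 41 rose and 4 fell (23 and 6 adjusted over the list alone, 24 and 8 with the replicate block). Its median log2 fold change was 0.89 (camera adjusted p = 7.27e-10). Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975, plus strand) rose by 6.47 ± 0.39, Ptgs2, the inducible cyclooxygenase gene, by 2.48 ± 0.19 and the hyaluronan receptor gene Cd44 by 0.89 ± 0.09. The matrix-degrading proteases and inhibitors were not called (9 of 30 rose, 4 fell, 10 and 8 adjusted over the list alone, 10 and 8 with the replicate block, camera adjusted p = 0.214), with a median of -0.0011 and a mean of 0.25. Among them Timp1, a protease inhibitor gene, rose from 117 ± 22.1 to 446 ± 68.2 CPM (1.93, adjusted p = 2.52e-05). The collagenase gene Mmp13 rose from 1.57 ± 1.15 to 19.1 ± 11.3 CPM (3.61, adjusted p = 0.00452).

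The largest falls were those of genes of macrophages and related blood cells. Fcrls, Pirb, Pou2f2, Pik3cg and Cd300lb had 0 counts in the FMK libraries. They were at least 265-, 72.6-, 70.2-, 66.2- and 34.2-fold lower than with DMSO (adjusted p = 1.25e-06 to 0.0119). The call of Fcrls was lost in another fit (adjusted p = 0.107 with only the 2 groups in the fit). Mrc1, the mannose receptor gene of macrophages, had 3 counts with FMK and 2565 with DMSO, a ratio of 789 (95% counting interval 269.8 to 3830.1). Of the macrophage and osteoclast markers, 0 of 23 rose and 22 fell (0 and 22 adjusted over the list alone). Together the members had a median log2 fold change of -6.03 (camera adjusted p = 7.66e-78). Log2 fold changes were -6.78 ± 0.24 for Tyrobp (ENSMUSG00000030579, chromosome 7, 30413760 to 30417585, plus strand), -3.64 ± 0.18 for the lysosomal glycoprotein gene Cd68 and -5.08 ± 0.27 for Spi1, the transcription factor PU.1.

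Other cell types did not move alike. Of the adipocyte markers, 0 of 16 rose and 9 fell (0 and 14 adjusted over the list alone, 0 and 14 with the replicate block). Over its members the median log2 fold change was -3.54 (camera adjusted p = 5.70e-06, and adjusted p = 0.427 with an estimated correlation). The adipocyte transcription factor gene Cebpa fell from 67.4 ± 26.3 to 15.3 ± 3.24 CPM (adjusted p = 0.0106). The lipoprotein lipase gene Lpl fell to 101 ± 31.5 CPM (adjusted p = 0.0219), a call lost with a library left out (adjusted p = 0.0635 to 0.0689 without DMSO replicates 1 and 2 or FMK replicates 1, 2 and 3). Within numbers 1, 2 and 3 the mean log2 level of the list with FMK differed from that with DMSO by -4.24, -3.78 and -1.98. Skeletal muscle markers were not called (0 of 27 rose, 0 fell, 0 and 0 adjusted over the list alone, 0 and 13 with the replicate block, camera adjusted p = 0.137, median -0.72, -1.45 to 0.099 with 1 library left out). They passed as lower under other settings (adjusted p = 0.00811 to 0.0154 without DMSO replicate 1 or FMK replicate 3, adjusted p = 0.000329 with the replicate number as a block and adjusted p = 0.0460 in the libraries numbered 1 and 2). With the block and an estimated correlation they did not (adjusted p = 0.351). Endothelial markers were not called (4 of 8 rose, 0 fell, 5 and 0 adjusted over the list alone, camera adjusted p = 0.214, median 0.74). Glial and melanocyte markers were not called (1 of 5 rose, 3 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.0628), but passed in another fit (adjusted p = 0.0437 without FMK replicate 2). Among them S100b fell from 21.2 ± 8.37 to 3.57 ± 0.414 CPM. The joint, tendon and perichondrium markers were not called (3 of 22 rose, 4 fell, 3 and 4 adjusted over the list alone, 5 and 9 with the replicate block, camera adjusted p = 0.194), although the tendon genes Col14a1 (-1.19 ± 0.10) and Tnmd (-1.95 ± 0.16) changed. Ectoderm and keratinocyte markers were not called (1 of 7 rose, 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.934).

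Many cartilage transcripts fell with FMK, in libraries where macrophage markers had a median log2 fold change of -6.03. Of the cartilage matrix genes, 0 of 25 rose and 15 fell (0 and 19 adjusted over the list alone). As a list it had a median log2 fold change of -1.18 (camera adjusted p = 7.27e-10, and adjusted p = 0.192 with an estimated correlation). Col2a1 (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695, minus strand) had a log2 fold change of -1.65 ± 0.30 (95% interval -2.39 to -0.91, adjusted p = 0.0113). Acan, the gene of the proteoglycan aggrecan, fell from 79.0 ± 19.7 to 23.2 ± 7.64 CPM (adjusted p = 0.00480). The smallest p belonged to Cilp2 (-1.31 ± 0.10), Prelp (-1.15 ± 0.15) and Matn4 (-0.98 ± 0.12), genes of extracellular matrix proteins. Sox9, the transcription factor gene that directs cartilage formation, fell from 470.1 ± 63.3 to 303 ± 28.6 CPM (adjusted p = 0.00212). The chondrogenic regulators were not called (2 of 21 rose, 4 fell, 2 and 4 adjusted over the list alone, camera adjusted p = 0.324), and their leading members were Sox6 (-1.32 ± 0.18) and Tgfb2 (0.57 ± 0.08).

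Genes of mineralizing cartilage and bone divided. Spp1, which encodes the matrix protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand), rose from 22.5 ± 3.24 to 543 ± 239 CPM (log2 fold change 4.59 ± 0.39, adjusted p = 0.000307). Enpp1, a pyrophosphate-generating enzyme gene, rose from 13.1 ± 0.450 to 57.1 ± 6.66 CPM. Col10a1, the collagen gene of hypertrophic cartilage, fell from 12.0 ± 3.42 to 6.13 ± 1.26 CPM (adjusted p = 0.0444). That call was lost under several settings (adjusted p = 0.0568 to 0.197 without DMSO replicates 1 and 3 or FMK replicates 1, 2 and 3, adjusted p = 0.0962 with limma-voom and adjusted p = 0.0964 in the libraries numbered 1 and 2). Runx2, a regulator of hypertrophy and bone, had a log2 fold change of 0.12 ± 0.26 (95% interval -0.43 to 0.68, adjusted p = 0.798). The hypertrophic cartilage list was not called (6 of 15 rose, 3 fell, 7 and 3 adjusted over the list alone, camera adjusted p = 0.104). It passed as higher under other settings (adjusted p = 0.0121 to 0.0489 without FMK replicates 1 and 3, adjusted p = 0.0242 with the stricter low-count filter and adjusted p = 0.0492 in the libraries numbered 1 and 2). The osteoblast list was not called (2 of 13 rose, 2 fell, 2 and 2 adjusted over the list alone, camera adjusted p = 0.681), with a median of -0.026 and a mean of 0.22. Its leading members were Spp1 and the pyrophosphate transport gene Ank (0.71 ± 0.13).

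Caspase genes moved in both directions. Casp9 (-0.29, adjusted p = 0.414) did not pass. Casp8, the initiator caspase gene of death receptors, rose by 0.61 ± 0.14 (adjusted p = 0.00380). Casp4, of the noncanonical inflammasome, rose by 2.78 ± 0.30. Casp1, of the canonical inflammasome, had 169 counts with DMSO and 2 with FMK, a ratio of 78 (95% counting interval 21.3 to 649), beside a macrophage median of -6.03. As a list the caspases were not called (3 of 9 rose, 1 fell, 3 and 1 adjusted over the list alone, camera adjusted p = 0.375), with a median of 0.0075 and a mean of -0.18. Apoptosis regulators were not called (7 of 28 rose, 3 fell, 7 and 3 adjusted over the list alone, camera adjusted p = 0.481), and the first by p was Tnfrsf1a (0.56 ± 0.08). Of the necroptosis and pyroptosis genes, 6 of 14 rose and 2 fell (6 and 2 adjusted over the list alone). The median log2 fold change was 0.17, 0.15 to 0.34 with 1 library left out (camera adjusted p = 3.98e-05, 0.165 with an estimated correlation, 0.0379 with that and the block). The RNA receptor gene Tlr3 (3.44 ± 0.18) and Mlkl, effector of necroptosis (3.53 ± 0.25), rose. Other lists share 3 members, and a rise apart from interferon genes was not tested.

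Some lists of stress and metabolic genes were called at the preset correlation. Of the glycolysis and hypoxia genes, 21 of 31 rose and 0 fell (25 and 0 adjusted over the list alone). Taken over the list, the median log2 fold change was 0.60 (camera adjusted p = 5.18e-10, and adjusted p = 0.192 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 1.36 ± 0.11 and the pyruvate kinase gene Pkm by 0.77 ± 0.08. Of the p53 targets, 12 of 24 rose and 2 fell (15 and 2 adjusted over the list alone). Across the list the median log2 fold change was 0.49 (camera adjusted p = 0.00607, and adjusted p = 0.288 with an estimated correlation). Sesn1 (-1.33 ± 0.16) had the smallest p, followed by the apoptosis activator gene Bbc3 (0.68 ± 0.11). Of the integrated stress response and amino acid genes, 8 of 34 rose and 5 fell (9 and 5 adjusted over the list alone). The list's median log2 fold change was 0.13, 0.034 to 0.19 with 1 library left out (camera adjusted p = 0.0380, and adjusted p = 0.470 with an estimated correlation). The call was lost in other fits (adjusted p = 0.0608 to 0.276 without DMSO replicate 2 or FMK replicate 3, adjusted p = 0.0539 with the stricter low-count filter and adjusted p = 0.211 in the libraries numbered 1 and 2). The stress factor genes Atf3 (2.65 ± 0.20) and Ddit3 (1.02 ± 0.08) rose. Of the lysosome and cathepsin genes, 5 of 37 rose and 13 fell (6 and 14 adjusted over the list alone). Its median log2 fold change was -0.12, -0.16 to -0.070 with 1 library left out (camera adjusted p = 0.0159, and adjusted p = 0.427 with an estimated correlation). The call was lost with a library left out (adjusted p = 0.0540 without FMK replicate 3). Cd68, also a macrophage marker, fell and Sqstm1, an autophagy receptor gene, rose (0.86 ± 0.08), beside a macrophage median of -6.03.

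Of the cholesterol synthesis genes, 7 of 23 rose and 0 fell (7 and 0 adjusted over the list alone). Together the members had a median log2 fold change of 0.31, 0.20 to 0.40 with 1 library left out (camera adjusted p = 0.0408, and adjusted p = 0.451 with an estimated correlation). The list's call was lost elsewhere (adjusted p = 0.0716 to 0.140 without DMSO replicates 2 and 3 or FMK replicate 1, adjusted p = 0.0539 with the stricter low-count filter, adjusted p = 0.0544 with the replicate number as a block and adjusted p = 0.0973 in the libraries numbered 1 and 2). Of the endoplasmic reticulum chaperones, 0 of 21 rose and 7 fell (0 and 9 adjusted over the list alone). Over its members the median log2 fold change was -0.20 (camera adjusted p = 0.0499, and adjusted p = 0.297 with an estimated correlation). Sdf2l1 led them (-0.97 ± 0.16), and this list's call was lost too (adjusted p = 0.0612 to 0.0966 without DMSO replicates 1, 2 and 3 or FMK replicate 2, adjusted p = 0.0503 with RLE normalization, adjusted p = 0.0524 with the stricter low-count filter, adjusted p = 0.0636 with the replicate number as a block and adjusted p = 0.0665 in the libraries numbered 1 and 2). NRF2 and glutathione genes were not called (4 of 24 rose, 1 fell, 4 and 1 adjusted over the list alone, camera adjusted p = 0.776), with a median of -0.047 and a mean of 0.046. Their first member, the antioxidant enzyme gene Srxn1, rose (0.90 ± 0.11). Cell cycle genes (1 of 40 rose, 3 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.681) were not called. Nor were mitochondrially encoded genes (1 of 7 rose, 2 fell, 1 and 3 adjusted over the list alone, 1 and 4 with the replicate block, camera adjusted p = 0.375). Of the 13 lists called (8 higher, 5 lower), 4 were called with an estimated correlation. These were interferon response (0.0124), macrophage and osteoclast markers (0.0124), NF-kB targets (0.0216) and osteoarthritis-related mediators (0.0167). With the replicate number as a block as well, these were kept and necroptosis and pyroptosis genes were added (0.0379). Libraries of the groups did not overlap for 4702 genes (35.5%, against 10% by chance for unpaired libraries). With library size alone 2945 genes passed, 1012 higher and 1933 lower, so 34.4% were rises in place of 50.7%. By the authors' deposited table, 1326 genes were higher and 1328 lower at the same threshold. Of those 2654 genes, 2501 also passed here, 0 with the opposite sign.

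The comparison of OPH with DMSO asked the same question for the other inhibitor. OPH also raised interferon response genes, 41 of 42 members, and lowered macrophage transcripts, with Tyrobp at 12.3 ± 1.47 CPM against 118 ± 24.7 with DMSO (SD, n = 3). Of the p53 targets 17 of 24 rose. Among them Gdf15, a stress-induced secreted factor gene (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456, minus strand), went from 14.2 ± 1.46 to 85.1 ± 21.2 CPM. Of the cartilage matrix genes 12 of 25 fell, but the list was not called with an estimated correlation (adjusted p = 0.118) and Col2a1 did not pass (adjusted p = 0.0657). Nor did Spp1, at 30.5 ± 4.82 CPM against 22.5 ± 3.24 (adjusted p = 0.538). In all, 2215 of 13255 genes passed (16.7%), 1140 higher and 1075 lower, 351 and 325 of them at least 2-fold.

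Ifnb1 had 0 counts with DMSO and 3.97 ± 1.25 CPM with OPH, at least 25.5-fold higher (adjusted p = 1.43e-05). The largest rises included Cxcl10 (7.88 ± 0.48 on the log2 scale), Ccl5 (7.18 ± 0.33), Cxcl9, an interferon-induced chemokine gene (7.02 ± 0.47), and Mx1 (7.0 ± 0.55). Ecel1, a metalloprotease-like gene of neurons, had 2 counts with DMSO and 301 with OPH, a ratio of 144 (95% counting interval 39.6 to 1196). Cxcl11 had 2 and 408 counts, a ratio of 195 (95% counting interval 53.7 to 1619) (adjusted p = 0.00916). That call was lost elsewhere (adjusted p = 0.0741 without DMSO replicate 3, adjusted p = 0.0679 with limma-voom and adjusted p = 0.268 in the libraries numbered 1 and 2). Of the interferon response list, 41 of 42 rose and 0 fell (41 and 0 adjusted over the list alone). As a list it had a median log2 fold change of 4.04 (camera adjusted p = 4.00e-231). Gbp3 (4.92 ± 0.15), Ddx58 (2.60 ± 0.10) and Ifi35 (2.70 ± 0.11) had the smallest p. Of the NF-kB targets and chemokines, 18 of 25 rose and 0 fell (19 and 0 adjusted over the list alone). For the list the median log2 fold change was 0.98 (camera adjusted p = 3.48e-19, and adjusted p = 0.0676 with an estimated correlation and the block). Nfkbia (0.97 ± 0.10) and Saa3 (2.96 ± 0.31) led. Of the osteoarthritis-related mediators, 11 of 41 rose and 3 fell (11 and 6 adjusted over the list alone, 13 and 7 with the replicate block). Taken over the list, the median log2 fold change was 0.32, 0.21 to 0.48 with 1 library left out (camera adjusted p = 0.00362, and adjusted p = 0.118 with an estimated correlation). Leading members were Nampt, a NAD synthesis enzyme gene (1.44 ± 0.13), and Igfbp5, a binding protein of insulin-like growth factors (0.68 ± 0.07).

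The largest falls were again in macrophage genes. Log2 fold changes were -6.35 ± 0.66 for Mrc1, -6.08 ± 0.60 for the chemokine gene Pf4, -5.72 ± 0.62 for the scavenger receptor gene Stab1, -5.59 ± 0.80 for Wfdc17 and -4.98 ± 0.86 for Atp6v0d2, a proton pump gene of osteoclasts. The call of Wfdc17 (adjusted p = 0.00102) was lost with another tool (adjusted p = 0.0588 with limma-voom). Fcrls (-7.42, adjusted p = 0.0156) lost its call as well (adjusted p = 0.0675 to 0.0831 without OPH replicates 1, 2 and 3 and adjusted p = 0.0596 with limma-voom). Of the macrophage and osteoclast markers, 0 of 23 rose and 22 fell (0 and 23 adjusted over the list alone). Across the list the median log2 fold change was -2.76 (camera adjusted p = 2.12e-45). Tyrobp (-3.26 ± 0.17), Cd68 (-3.01 ± 0.17) and Spi1 (-2.09 ± 0.20) had the smallest p. Of the lysosome and cathepsin genes, 3 of 37 rose and 15 fell (4 and 18 adjusted over the list alone). The list's median log2 fold change was -0.25 (camera adjusted p = 3.24e-05, and adjusted p = 0.136 with an estimated correlation). Cd68 and the cathepsin C gene Ctsc (-1.45 ± 0.12) fell and Sqstm1 rose (1.13 ± 0.08).

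Adipocyte markers were not called (0 of 16 rose, 0 fell, 0 and 0 adjusted over the list alone, 2 and 2 with the replicate block, camera adjusted p = 0.728, median 0.043). Within numbers 1, 2 and 3 the list mean differed from that with DMSO by -0.25, 0.30 and 0.70. Skeletal muscle markers (0 of 27 rose, 0 fell, 0 and 0 adjusted over the list alone, 2 and 2 with the replicate block, camera adjusted p = 0.948) were not called. Nor were endothelial markers (0 of 8 rose, 1 fell, 0 and 1 adjusted over the list alone, camera adjusted p = 0.728), with a median of 0.031 and a mean of -0.14. Ectoderm and keratinocyte markers were not called (0 of 7 rose, 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.728). Glial and melanocyte markers were not called (1 of 5 rose, 1 fell, 1 and 1 adjusted over the list alone, camera adjusted p = 0.383), although S100b fell (-1.48, adjusted p = 0.00200). Of the joint, tendon and perichondrium markers, 0 of 22 rose and 8 fell (0 and 10 adjusted over the list alone, 1 and 13 with the replicate block). Its median log2 fold change was -0.42 (camera adjusted p = 0.000178, and adjusted p = 0.0868 with an estimated correlation and the block). The Wnt modulator gene Sfrp2 (-1.30 ± 0.13), Tnmd (-1.41 ± 0.15) and Col14a1 (-0.67 ± 0.10) led.

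Of the cartilage matrix genes, 0 of 25 rose and 12 fell (1 and 18 adjusted over the list alone, 1 and 20 with the replicate block), beside a macrophage median of -2.76. Together the members had a median log2 fold change of -1.09 (camera adjusted p = 7.54e-10, and adjusted p = 0.118 with an estimated correlation). Matn4 (-1.31 ± 0.13), Cilp2 (-0.85 ± 0.10) and Hapln1, the link protein gene of aggrecan (-1.50 ± 0.20), led. Col2a1 was at 648 ± 244 CPM and did not pass (-1.04, adjusted p = 0.0657). It passed elsewhere (adjusted p = 0.00494 without OPH replicate 3, adjusted p = 0.00590 with DESeq2, adjusted p = 0.00332 with limma-voom and adjusted p = 0.0392 in the libraries numbered 1 and 2). Acan fell to 36.0 ± 10.8 CPM (adjusted p = 0.0353), a call lost with a library left out (adjusted p = 0.0877 to 0.117 without DMSO replicates 1 and 3 or OPH replicates 1 and 2). Sox9 fell to 313 ± 49.6 CPM (adjusted p = 0.00475). The chondrogenic regulators were not called (2 of 21 rose, 4 fell, 2 and 4 adjusted over the list alone, camera adjusted p = 0.383), with Tgfb2 higher (0.64 ± 0.08) and Bmp4 lower (-0.51 ± 0.09). The hypertrophic cartilage list was not called either (0 of 15 rose, 0 fell, 0 and 0 adjusted over the list alone, 2 and 3 with the replicate block, camera adjusted p = 0.728). In it, Col10a1 (-0.36, adjusted p = 0.510), Mmp13 (1.00, adjusted p = 0.441), Runx2 (-0.14, adjusted p = 0.799) and Spp1 (0.44, adjusted p = 0.538) did not pass.

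The osteoblast list was not called (0 of 13 rose, 5 fell, 0 and 6 adjusted over the list alone, camera adjusted p = 0.0625), but passed as lower under other settings (adjusted p = 0.0224 to 0.0465 without DMSO replicate 2 or OPH replicate 3, adjusted p = 0.0125 with the stricter low-count filter and adjusted p = 0.0485 in the libraries numbered 1 and 2). Its members Sparc (-0.43 ± 0.06) and Col1a1 (-0.43 ± 0.07), genes of bone and connective tissue matrix, fell. Proteases and inhibitors were not called (3 of 30 rose, 6 fell, 3 and 6 adjusted over the list alone, camera adjusted p = 0.0903), but passed as lower elsewhere (adjusted p = 0.0449 without DMSO replicate 2). The urokinase gene Plau fell (-1.47 ± 0.26). Casp8 (0.16, adjusted p = 0.507) and Casp9 (-0.26, adjusted p = 0.501) did not pass. The caspases were not called as a list (1 of 9 rose, 1 fell, 2 and 1 adjusted over the list alone, camera adjusted p = 0.728), with Casp4 higher (2.22 ± 0.30) and Casp1 lower (-2.12 ± 0.45, beside a macrophage median of -2.76). Apoptosis regulators were not called (7 of 28 rose, 2 fell, 7 and 3 adjusted over the list alone, camera adjusted p = 0.0640), but passed as higher elsewhere (adjusted p = 0.0449 without DMSO replicate 2). The pro-apoptotic genes Bbc3 (1.47 ± 0.11) and Bcl2l11 (0.90 ± 0.13) rose. Of the necroptosis and pyroptosis genes, 5 of 14 rose and 2 fell (5 and 3 adjusted over the list alone). The median log2 fold change was 0.15, 0.13 to 0.25 with 1 library left out (camera adjusted p = 0.000502, 0.118 with an estimated correlation). Tlr3 (3.47 ± 0.18) and Mlkl (2.80 ± 0.26) rose, with the same limits.

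Several stress lists were called higher with the preset correlation. Among p53 targets 17 of 24 rose and 2 fell (17 and 2 adjusted over the list alone). As a list it had a median log2 fold change of 0.63 (camera adjusted p = 4.30e-10, and adjusted p = 0.0687 with an estimated correlation and the block). Gdf15 (2.58 ± 0.18), Bbc3 and Trp53inp1 (1.54 ± 0.13) led. Among integrated stress response and amino acid genes 15 of 34 rose and 0 fell (17 and 0 adjusted over the list alone). For the list the median log2 fold change was 0.34 (camera adjusted p = 7.91e-09, and adjusted p = 0.118 with an estimated correlation). Ddit3 (1.29 ± 0.08), Atf3 (2.96 ± 0.20) and the pseudokinase gene Trib3 (1.13 ± 0.10) led. Among NRF2 and glutathione genes 7 of 24 rose and 0 fell (10 and 1 adjusted over the list alone, 12 and 2 with the replicate block). Taken over the list, the median log2 fold change was 0.36 (camera adjusted p = 0.000983, and adjusted p = 0.118 with an estimated correlation). Srxn1 (1.29 ± 0.11) and the heme oxygenase gene Hmox1 (1.12 ± 0.10) led. Among cholesterol synthesis genes 4 of 23 rose and 0 fell (4 and 0 adjusted over the list alone, 10 and 0 with the replicate block). Across the list the median log2 fold change was 0.28 (camera adjusted p = 0.0269, and adjusted p = 0.403 with an estimated correlation). That call was lost with a library left out (adjusted p = 0.0747 to 0.0925 without DMSO replicate 2 or OPH replicate 1). Among endoplasmic reticulum chaperones 0 of 21 rose and 12 fell (0 and 12 adjusted over the list alone), led by Sdf2l1 (-1.19 ± 0.16). The list's median log2 fold change was -0.31 (camera adjusted p = 0.000302, and adjusted p = 0.0828 with an estimated correlation). Among cell cycle genes 0 of 40 rose and 9 fell (0 and 12 adjusted over the list alone), led by the replication gene Mcm4 (-0.59 ± 0.12). Its median log2 fold change was -0.25, -0.32 to -0.16 with 1 library left out (camera adjusted p = 0.000983, and adjusted p = 0.291 with an estimated correlation). Among mitochondrially encoded genes 0 of 7 rose and 4 fell (0 and 5 adjusted over the list alone), led by mt-Nd2 (-0.55 ± 0.08). Together the members had a median log2 fold change of -0.55 (camera adjusted p = 0.00529, and adjusted p = 0.314 with an estimated correlation). Glycolysis and hypoxia genes were not called (5 of 31 rose, 1 fell, 5 and 1 adjusted over the list alone, camera adjusted p = 0.557), although Slc2a1 rose (0.74 ± 0.11).

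Of the 15 lists called (8 higher, 7 lower), 5 were called with an estimated correlation. These were interferon response (0.00688), macrophage and osteoclast markers (0.0265), NF-kB targets (0.0413), p53 targets (0.0413) and joint, tendon and perichondrium markers (0.0413). With the replicate number as a block as well, the calls of NF-kB targets (0.0676), p53 targets (0.0687) and joint markers (0.0868) were lost, and those of interferon response (0.00910) and macrophage markers (0.0335) were kept. Libraries of the groups did not overlap for 4469 genes (33.7%, against 10% by chance for unpaired libraries). By the authors' deposited table, 1070 genes were higher and 1080 lower at the same threshold. Of those 2150 genes, 2032 also passed here, 0 with the opposite sign.

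Fold changes against DMSO with the 2 inhibitors were correlated across the 13255 genes (Pearson r = 0.766), which are not independent replicates, and both comparisons share 3 controls. Unchanged groups simulated against those controls gave a mean r of 0.501 (0.481 to 0.549 in 20 simulations). The covariance was 0.604 against a simulated 0.0546, a difference of 0.549. Both inhibitors raised 719 genes and lowered 646, where independent lists of these sizes would share 119 and 109. In opposite directions 8 genes were called, against 227 for independent lists. The 3 controls cannot be divided with 2 or more in each part, so part of the excess may come from the shared controls. Of the 8, chosen after their values were seen, the integrin gene Itgb3 (0.69 ± 0.16 with FMK and -0.71 ± 0.17 with OPH) and the vimentin gene Vim (0.29 ± 0.06 and -0.30 ± 0.06) kept both calls with each library left out. The others lost 1 or both calls. With FMK these were Chodl (adjusted p = 0.0850 to 0.30 without DMSO replicates 1 and 3 or FMK replicates 1, 2 and 3), Mgp (adjusted p = 0.0863 to 0.148 without DMSO replicates 1 and 2 or FMK replicates 1 and 2), Tsc22d3 (adjusted p = 0.0529 to 0.0808 without DMSO replicates 1 and 2 or FMK replicate 1) and Tpm1 (adjusted p = 0.0746 to 0.167 without DMSO replicates 1 and 2 or FMK replicates 2 and 3). With OPH they were Tpm1 (adjusted p = 0.0762 to 0.161 without DMSO replicates 2 and 3 or OPH replicates 1 and 2), Tenm4 (adjusted p = 0.0555 to 0.0813 without DMSO replicates 1 and 3 or OPH replicate 2) and Lgals1 (adjusted p = 0.0650 to 0.118 without DMSO replicate 3 or OPH replicates 1 and 2).

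**Figure D2:**
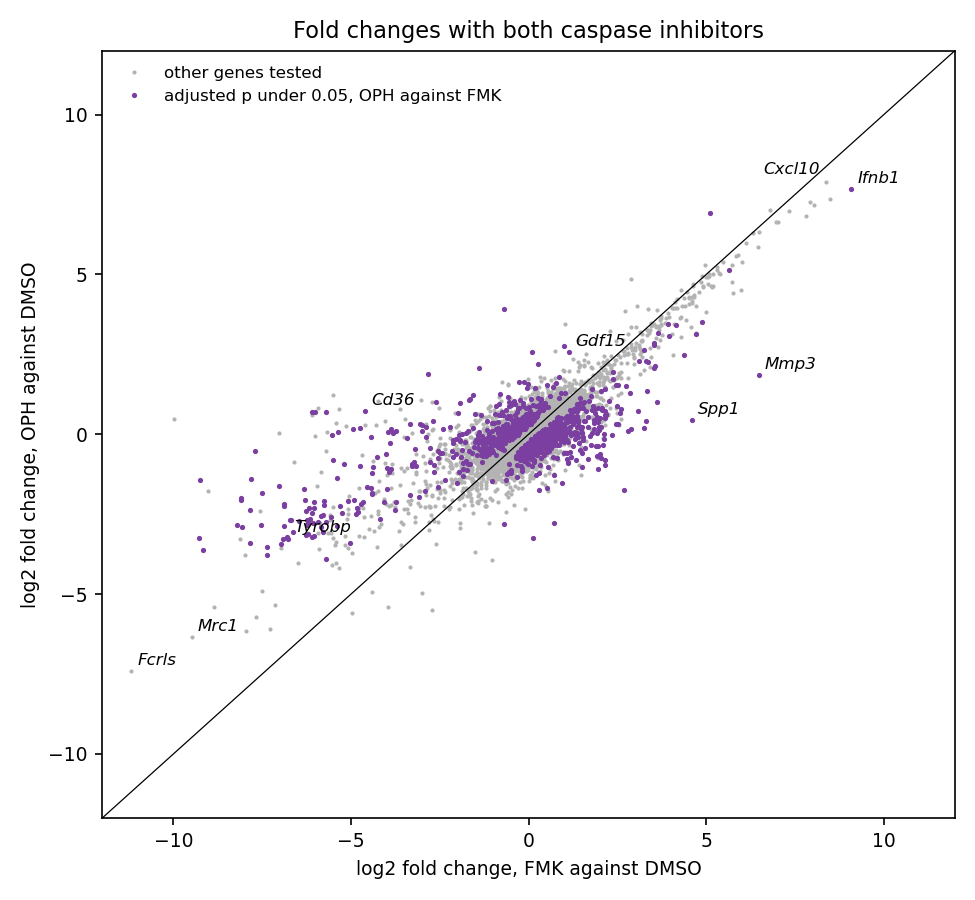
Log2 fold change with OPH against DMSO (vertical axis) and with FMK against DMSO (horizontal axis) for each of the 13255 genes tested; the line marks equal values and purple points passed an adjusted p of 0.05 between OPH and FMK. Spp1 lies at 4.59 with FMK and 0.44 with OPH, Gdf15 at 1.13 and 2.58, and Cxcl10 at 8.37 and 7.88.

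OPH and FMK were compared directly at the same dose and time. FMK carries the peptide Val-Ala-Asp with a fluoromethyl ketone, and OPH carries Val-Asp with a difluorophenoxymethyl ketone and a quinoline cap. Macrophage transcripts were less depleted with OPH, with Tyrobp at 12.3 ± 1.47 CPM against 1.07 ± 0.408 with FMK (SD, n = 3). Mmp3 was at 1.73 ± 0.547 against 42.5 ± 15.9 CPM with FMK and Spp1 at 30.5 ± 4.82 against 543 ± 239 CPM. Gdf15 was higher, at 85.1 ± 21.2 against 31.1 ± 4.68 CPM. In all, 1175 of 13255 genes differed (8.86%), 557 higher and 618 lower with OPH, 219 and 139 of them at least 2-fold. With the replicate number as a block 2139 differed, 1031 higher and 1108 lower, with 1174 of the 1175 among them.

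**Figure D3:**
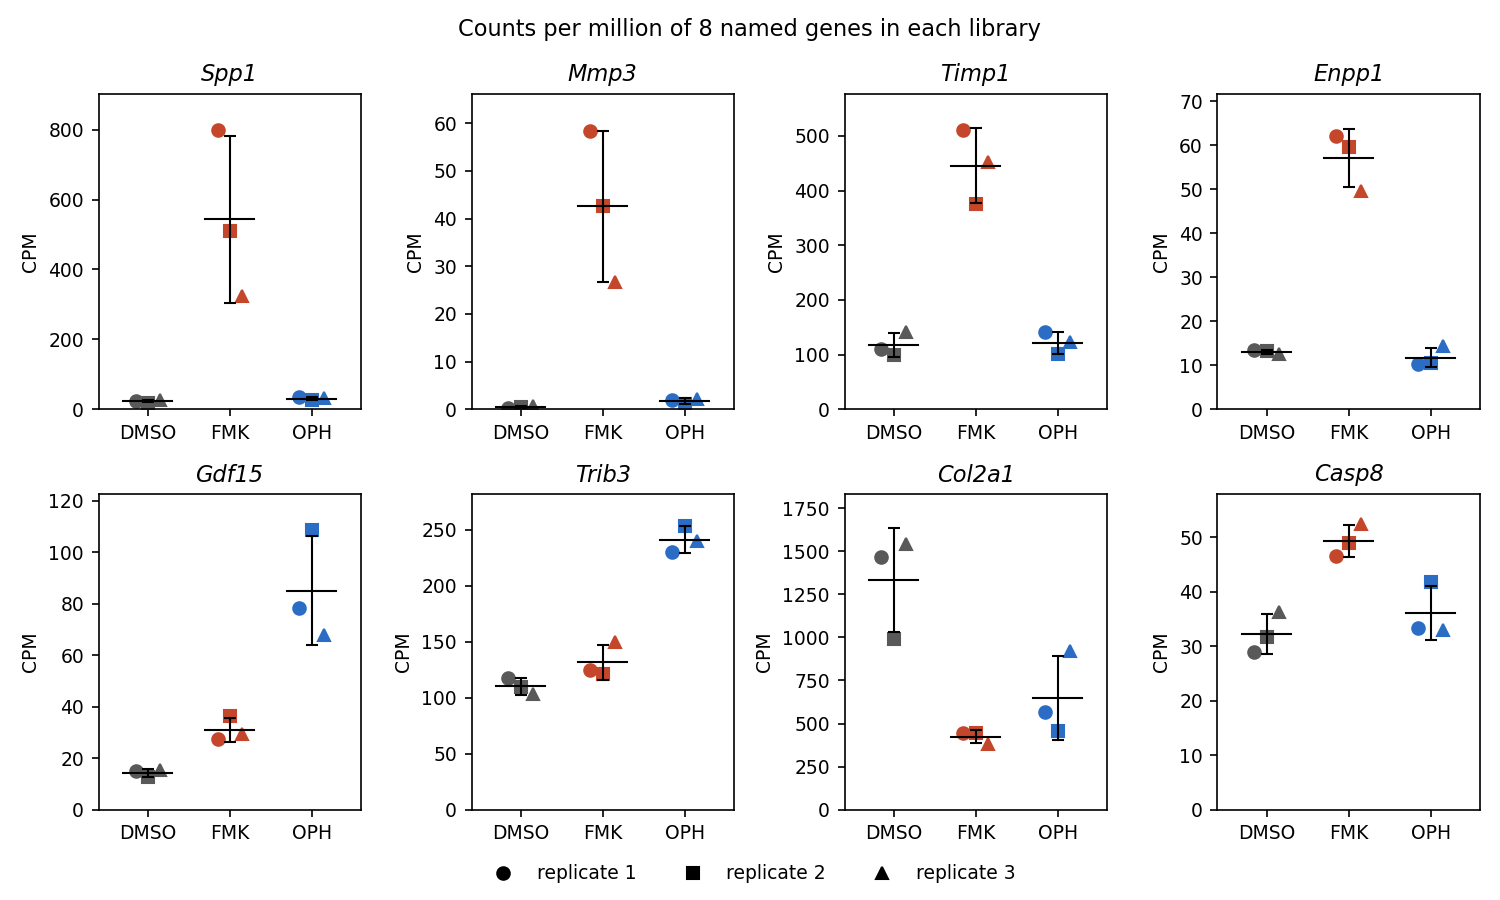
CPM of 8 named genes in each library, by group; symbols mark the replicate number, the horizontal line is the group mean and the bar its SD (n = 3), and each axis starts at 0. Spp1, Mmp3, Timp1 and Enpp1 were highest with FMK (means of 543, 42.5, 446 and 57.1 CPM), Gdf15 and Trib3 with OPH (85.1 and 241 CPM) and Col2a1 with DMSO (1333 CPM), and Casp8 means were 32.3, 49.4 and 36.1 CPM.

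Among macrophage and osteoclast markers 16 of 23 rose and 0 fell (20 and 0 adjusted over the list alone). Over its members the median log2 fold change was 2.99 (camera adjusted p = 9.74e-50). Tyrobp (3.52 ± 0.28), Spi1 (2.99 ± 0.29) and the endotoxin co-receptor gene Cd14 (2.28 ± 0.28) were higher with OPH. Ptprc, the pan-leukocyte gene CD45, had 2 counts with FMK and 113 with OPH, a ratio of 50.0 (95% counting interval 13.5 to 418). Genes of fat cells were among the largest differences, but their calls were lost elsewhere. Mrap, an accessory protein gene of melanocortin receptors, had 2 and 301 counts, a ratio of 133 (95% counting interval 36.5 to 1104) (adjusted p = 0.0330). Other settings gave adjusted p = 0.0638 to 0.155 without FMK replicates 1, 2 and 3 or OPH replicates 1 and 2, adjusted p = 0.0568 with no low-count filter and adjusted p = 0.116 with limma-voom. Aqp7, a glycerol channel gene, had 1 and 133 counts, a ratio of 118 (95% counting interval 20.7 to 4679.9) (adjusted p = 0.00753). Its call ended with adjusted p = 0.0601 to 0.0829 without FMK replicates 1 and 2 and adjusted p = 0.0554 with limma-voom. The fatty acid transporter gene Cd36 was at 54.6 ± 32.9 against 1.35 ± 0.440 CPM (adjusted p = 0.0302). That call ended with adjusted p = 0.0778 to 0.112 without FMK replicates 1, 2 and 3 or OPH replicates 1 and 2 and adjusted p = 0.148 with limma-voom. The fatty acid receptor gene Ffar2 (5.54, adjusted p = 0.0132) lost its call with adjusted p = 0.0524 to 0.0545 without FMK replicates 1 and 2. Nat8l (4.94, adjusted p = 0.0303) lost it with adjusted p = 0.0629 to 0.125 without FMK replicates 1 and 2 or OPH replicates 1 and 2 and adjusted p = 0.119 with limma-voom. Among adipocyte markers 3 of 16 rose and 0 fell (16 and 0 adjusted over the list alone, 15 and 0 with the replicate block). As a list it had a median log2 fold change of 4.15 (camera adjusted p = 2.01e-15, and adjusted p = 0.145 with an estimated correlation but adjusted p = 0.0409 with that and the block).

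Among skeletal muscle markers 0 of 27 rose and 0 fell (0 and 0 adjusted over the list alone, 12 and 0 with the replicate block). For the list the median log2 fold change was 0.76, 0.14 to 1.39 with 1 library left out (camera adjusted p = 0.0122, and adjusted p = 0.657 with an estimated correlation). The call was lost in other fits (adjusted p = 0.324 to 0.375 without FMK replicate 1 or OPH replicate 3). Among endothelial markers 0 of 8 rose and 3 fell (0 and 4 adjusted over the list alone). Taken over the list, the median log2 fold change was -0.60 (camera adjusted p = 0.00445, and adjusted p = 0.101 with an estimated correlation). The endothelial genes that passed lost their calls elsewhere. For Ecscr this was adjusted p = 0.0511 to 0.0546 without FMK replicate 2 or OPH replicate 2. For Flt1 it was adjusted p = 0.0576 to 0.0693 without FMK replicates 1 and 2 or OPH replicates 2 and 3. For Plvap it was adjusted p = 0.0599 to 0.114 without FMK replicates 1 and 2 or OPH replicates 1, 2 and 3 and adjusted p = 0.0801 with only the 2 groups in the fit. Among joint, tendon and perichondrium markers 1 of 22 rose and 6 fell (3 and 8 adjusted over the list alone, 3 and 10 with the replicate block). Across the list the median log2 fold change was -0.29 (camera adjusted p = 0.00338, and adjusted p = 0.0808 with an estimated correlation). Col14a1 was higher (0.52 ± 0.10) and Thbs4, a thrombospondin gene of tendon, lower (-2.67 ± 0.34). Glial and melanocyte markers were not called (0 of 5 rose, 0 fell, 2 and 0 adjusted over the list alone, 2 and 0 with the replicate block, camera adjusted p = 0.0511), but passed elsewhere (adjusted p = 0.0214 to 0.0247 without FMK replicate 2 or OPH replicate 2 and adjusted p = 0.0497 with RLE normalization). Ectoderm and keratinocyte markers were not called (0 of 7 rose, 1 fell, 0 and 1 adjusted over the list alone, camera adjusted p = 0.698).

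Among matrix-degrading proteases and inhibitors 0 of 30 rose and 8 fell (0 and 11 adjusted over the list alone, 0 and 13 with the replicate block). The list's median log2 fold change was -0.34 (camera adjusted p = 1.09e-06). Mmp3 (-4.62, adjusted p = 5.71e-07), Timp1 (-1.87 ± 0.17) and the tissue plasminogen activator gene Plat (-1.13 ± 0.19) led. Among osteoarthritis-related mediators 2 of 41 rose and 15 fell (3 and 18 adjusted over the list alone). Its median log2 fold change was -0.67 (camera adjusted p = 1.61e-10). After Mmp3 came Ptgs2 (-1.58 ± 0.18), Cd44 (-0.67 ± 0.09) and Cxcl1 (-1.90 ± 0.27). Among NF-kB targets and chemokines 0 of 25 rose and 9 fell (0 and 14 adjusted over the list alone, 0 and 15 with the replicate block). Together the members had a median log2 fold change of -0.82 (camera adjusted p = 6.72e-12, and adjusted p = 0.0808 with an estimated correlation). Other large falls were those of the protease inhibitor gene Slpi, at 1.41 ± 1.05 against 30.4 ± 15.1 CPM, Spp1 (-4.16, adjusted p = 0.00171) and the EGF receptor ligand gene Ereg (-2.72 ± 0.36). The urea transporter gene Slc14a1 (-3.10, adjusted p = 0.00524) lost its call elsewhere (adjusted p = 0.0552 without FMK replicate 1). So did Prg4, the gene of the joint lubricant lubricin (-3.05, adjusted p = 0.0104, but adjusted p = 0.0541 without OPH replicate 2).

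Among hypertrophic cartilage genes 0 of 15 rose and 3 fell (0 and 3 adjusted over the list alone). Over its members the median log2 fold change was -0.21, -0.23 to -0.12 with 1 library left out (camera adjusted p = 0.000484, and adjusted p = 0.159 with an estimated correlation). Enpp1 (-2.28 ± 0.16) and Spp1 led, while Mmp13 (-2.61, adjusted p = 0.0299) lost its call elsewhere (adjusted p = 0.0659 to 0.125 without FMK replicate 2 or OPH replicates 2 and 3). Among osteoblast genes 0 of 13 rose and 5 fell (0 and 5 adjusted over the list alone). As a list it had a median log2 fold change of -0.26, -0.36 to -0.085 with 1 library left out (camera adjusted p = 0.000445, and adjusted p = 0.0808 with an estimated correlation). Ank (-1.05 ± 0.13) and Sparc (-0.40 ± 0.06) led. Cartilage matrix genes were not called (3 of 25 rose, 2 fell, 3 and 2 adjusted over the list alone, 8 and 3 with the replicate block, camera adjusted p = 0.212), but passed as higher elsewhere (adjusted p = 0.00281 without OPH replicate 2). The glycosaminoglycan synthesis gene Xylt1 was higher (0.89 ± 0.16). Chondrogenic regulators were not called (2 of 21 rose, 1 fell, 3 and 1 adjusted over the list alone, camera adjusted p = 0.698), with a median of 0.041 and a mean of -0.020. Sox6 was higher (1.12 ± 0.18).

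The interferon response list was called lower with OPH at the preset correlation, by a small median. Among interferon response genes 0 of 42 rose and 2 fell (0 and 1 adjusted over the list alone, 1 and 9 with the replicate block). For the list the median log2 fold change was -0.27, -0.37 to -0.15 with 1 library left out (camera adjusted p = 0.00113, and adjusted p = 0.557 with an estimated correlation). The 95% intervals of the log2 difference were -0.30 to 0.17 for Gbp3, -0.25 to 0.13 for Ddx58, -0.27 to 0.14 for Ifi35 and -1.23 to 0.25 for Cxcl10. Isg20 (-0.74, adjusted p = 0.0169) passed, but adjusted p = 0.0591 to 0.101 without FMK replicates 1 and 2 or OPH replicate 3. Oas3 (-1.46, adjusted p = 0.0352) passed, but adjusted p = 0.0554 to 0.170 without FMK replicates 1 and 2 or OPH replicates 1, 2 and 3. Ifnb1 was lower with OPH (-1.40, adjusted p = 0.0250), a call likewise lost (adjusted p = 0.0844 to 0.109 without FMK replicates 1 and 2 or OPH replicates 1 and 2). Differences in Col2a1 (0.61, 95% interval -0.11 to 1.33), Acan (0.63, -0.093 to 1.36) and Sox9 (0.047, -0.22 to 0.31) did not pass. With the replicate number as a block Acan was higher (adjusted p = 0.0188). The caspases were not called as a list (1 of 9 rose, 2 fell, 1 and 2 adjusted over the list alone, camera adjusted p = 0.383), with a median of -0.077 and a mean of 0.22. Casp1 had 2 counts with FMK and 40 with OPH, a ratio of 17.7 (95% counting interval 4.59 to 151), beside a macrophage median of 2.99.

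Lists of stress genes were called higher with OPH, and those of glycolysis, cell cycle and mitochondrially encoded genes lower, at the preset correlation. Without the block none of these calls held with an estimated correlation. For p53 targets 6 of 24 rose and 0 fell (7 and 0 adjusted over the list alone). Taken over the list, the median log2 fold change was 0.21 (camera adjusted p = 7.71e-05, and adjusted p = 0.107 with an estimated correlation). Gdf15 (1.45 ± 0.17), Trp53inp1 (1.03 ± 0.13) and Bbc3 (0.79 ± 0.11) led. For integrated stress response and amino acid genes 10 of 34 rose and 1 fell (15 and 2 adjusted over the list alone). Across the list the median log2 fold change was 0.29 (camera adjusted p = 3.38e-05, and adjusted p = 0.214 with an estimated correlation). Trib3 (0.87 ± 0.10) and Sesn2 (0.71 ± 0.12) led. For NRF2 and glutathione genes 6 of 24 rose and 1 fell (8 and 1 adjusted over the list alone, 10 and 1 with the replicate block). The list's median log2 fold change was 0.36 (camera adjusted p = 4.62e-05, and adjusted p = 0.0808 with an estimated correlation but adjusted p = 0.0409 with that and the block). Hmox1 (0.77 ± 0.10) and Gclc, a glutathione synthesis gene (0.90 ± 0.14), led. For glycolysis and hypoxia genes 0 of 31 rose and 16 fell (0 and 21 adjusted over the list alone). Its median log2 fold change was -0.54 (camera adjusted p = 1.33e-19, and adjusted p = 0.0750 with an estimated correlation). Pkm (-0.80 ± 0.08) and the lactate transporter gene Slc16a3 (-1.71 ± 0.17) led. For cell cycle genes 0 of 40 rose and 4 fell (0 and 5 adjusted over the list alone, 0 and 9 with the replicate block). Together the members had a median log2 fold change of -0.25 (camera adjusted p = 0.000111, and adjusted p = 0.214 with an estimated correlation). The centromere protein gene Cenpf (-0.46, adjusted p = 0.0211) lost its call elsewhere (adjusted p = 0.0503 to 0.105 without FMK replicate 2 or OPH replicates 1 and 2 and adjusted p = 0.0630 with library size alone). For mitochondrially encoded genes 0 of 7 rose and 1 fell (0 and 4 adjusted over the list alone, 0 and 4 with the replicate block). Over its members the median log2 fold change was -0.25 (camera adjusted p = 0.0180, and adjusted p = 0.372 with an estimated correlation). That call was lost as well (adjusted p = 0.0525 to 0.0874 without FMK replicates 1 and 3 or OPH replicate 2).

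Apoptosis regulators were not called (3 of 28 rose, 0 fell, 3 and 1 adjusted over the list alone, camera adjusted p = 0.164), with Bcl2l11 higher (0.67 ± 0.13). Lysosome and cathepsin genes were not called (2 of 37 rose, 7 fell, 4 and 8 adjusted over the list alone, camera adjusted p = 0.141), with the tetraspanin gene Cd63 lower (-0.46 ± 0.06). Necroptosis and pyroptosis genes were not called (1 of 14 rose, 2 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.0588), but passed as lower elsewhere (adjusted p = 0.0300 to 0.0343 without FMK replicate 3 or OPH replicate 2, adjusted p = 0.0222 with the replicate number as a block and adjusted p = 0.0402 in the libraries numbered 1 and 2). With the block and an estimated correlation they did not pass (adjusted p = 0.137). The kinase gene Ripk3 was lower (-0.96 ± 0.15). Endoplasmic reticulum chaperones were not called (2 of 21 rose, 3 fell, 2 and 6 adjusted over the list alone, camera adjusted p = 0.0990), but passed as lower elsewhere (adjusted p = 0.0391 without FMK replicate 2). Cholesterol synthesis genes were not called (0 of 23 rose, 0 fell, 0 and 0 adjusted over the list alone, camera adjusted p = 0.698). Of the 17 lists called (6 higher, 11 lower), 3 were called with an estimated correlation. These were macrophage and osteoclast markers (0.0126), osteoarthritis-related mediators (0.0126) and proteases and inhibitors (0.0126). With the replicate number as a block as well, these were kept and adipocyte markers (0.0409) and NRF2 and glutathione genes (0.0409) were added. The count of genes depended on single libraries, with 715 without FMK replicate 1, 721 without FMK replicate 2 and 570 without OPH replicate 2. With library size alone 1488 genes differed, 1103 higher and 385 lower, so 74.1% were higher in place of 47.4%. Libraries of the groups did not overlap for 3595 genes (27.1%, against 10% by chance for unpaired libraries). By the authors' deposited table, 606 genes were higher and 700 lower with OPH. Of those 1306 genes, 1144 also passed here, 0 with the opposite sign.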

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

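The tests of macrophage loss against replicate numbers and against other cell types were chosen after the result was seen, and the test of scaling was chosen before it.

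In 3 lists the effect of OPH against DMSO differed from that of FMK against DMSO by a camera test of the difference itself, with preset and with estimated correlation. The macrophage and osteoclast markers were higher with OPH by a median of 2.99 on the log2 scale (adjusted p = 0.0126 with an estimated correlation). The osteoarthritis-related mediators differed by -0.67 (adjusted p = 0.0126), and the matrix-degrading proteases and inhibitors by -0.34 (adjusted p = 0.0126).

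Macrophage and osteoclast markers fell with both inhibitors, by medians of -6.03 and -2.76 on the log2 scale. The other scalings moved the list by only -0.10 to 0.11 (smaller fall -2.75), too little to test scaling. Within equal replicate numbers the difference nearest to 0 was -2.56. Every group holds each number, so this value cannot test a difference between numbers. A loss of all cell types other than cartilage with FMK would have lowered the markers of each. Adipocyte and glial medians were -3.54 and -1.78. The muscle median was -0.72 (-1.45 to 0.099 with 1 library left out, 13 of 27 lower with the block). Endothelial markers had 0.74 (4 of 8 rose, list not called). A loss of all or several types stays open. The cultures may hold fewer macrophages, or macrophages with lower transcript levels, and neither this nor a direct effect of the compounds was tested.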

How the results depend on the processing

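The libraries numbered 1 and 2 alone, and the block with the estimated correlation, were chosen after the data were seen. Counts of genes changed stayed within 1.5 times under RLE scaling, both tools, the stricter filter and only the 2 groups in the fit. A minimum fold of 1.5, a stricter question by construction, left 808, 480 and 118 genes for FMK against DMSO, OPH against DMSO and OPH against FMK. With 1 library left out, genes that differed between OPH and FMK numbered 570 (without OPH replicate 2) to 1045. FMK replicates 1 and 2 left out singly gave 715 and 721. The correlation of fold changes was 0.846 among genes called in either comparison. Of 281 values of named genes, 280 kept direction and side of the threshold with RLE scaling, 269 with library size alone, 276 with DESeq2, 263 with limma-voom and 258 in the libraries numbered 1 and 2. The minimum fold ended 132 calls. Alternatives planned for normalized values, a pseudocount and a low-value filter, were not run because the values are counts. Depth limits genes near the floor of 0.147 to 0.166 CPM.

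With the replicate number as a block, 2139 genes differed between OPH and FMK in place of 1175, and the cause was not tested. The block ended 2 list calls, of cholesterol synthesis and endoplasmic reticulum chaperones with FMK against DMSO, and added 2, of skeletal muscle with FMK against DMSO and of necroptosis and pyroptosis with OPH against FMK, both lost with an estimated correlation (0.351 and 0.137). Among these values of named genes it ended 1 call, of Mgp with FMK (adjusted p = 0.0609), and added 1 (Junb OPH against FMK, adjusted p = 0.0197). Acan, outside these values, also passed with the block for OPH against FMK (adjusted p = 0.0188). An estimated correlation left 4, 5 and 3 lists called in the comparisons, 33 fewer in all. Lists so lost with FMK against DMSO had estimates of 0.037 to 0.89, above the preset. With the block it left 5, 2 and 5 (cause not tested).

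Some results changed direction, none of them called in the main test, and the cause was not tested. List directions are those of camera, so a median can keep its sign. In the libraries numbered 1 and 2, medians were -0.058 for NRF2 and -0.10 for joint markers with FMK against DMSO, 0.083 for muscle with OPH against DMSO, and -0.051 for chondrogenic regulators, -0.059 for cholesterol synthesis and 0.11 for ectoderm with OPH against FMK. The stricter filter gave -0.023 for ectoderm with FMK. With single libraries left out, ranges with FMK against DMSO were -0.094 to 0.016 for NRF2, -0.32 to 0.22 for ectoderm and -0.053 to 0.31 for Runx2. With OPH against DMSO they were -0.29 to 0.017 for hypertrophic cartilage, -0.0019 to 0.14 for glycolysis, -0.70 to 0.67 for muscle, -0.44 to 0.50 for adipocytes and -0.52 to 0.043 for Runx2. With OPH against FMK they were -0.081 to 0.079 for chondrogenic regulators, -0.055 to -0.0075 for cholesterol synthesis and -0.25 to 0.24 for ectoderm.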

Other observations

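The gene groups and genes of the first 2 paragraphs, and the tests of preparations, of more macrophages and of the interferon response as a cause, were chosen after the results were seen. Genes of antigen presentation by MHC class I rose together, 16 of 16 with FMK (median log2 fold change 3.56) and 16 of 16 with OPH (3.28). B2m, the invariant chain of class I molecules, rose from 1350.0 ± 168 CPM (SD, n = 3) to 6696 ± 568 with FMK and 5892 ± 443 with OPH, and H2-K1 rose by 3.63 and 3.39 on the log2 scale. Between OPH and FMK 0 of the 16 were higher and 1 lower (4 lower with the replicate number as a block). Reads of interferon genes were few, with 190 counts of Ifnb1 with FMK and 80 with OPH, 7 and 4 counts over 14 interferon alpha genes, and 0 of the interferon gamma and lambda genes.

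Immediate early genes and ligands of the EGF receptor rose in 11 of 16 cases with FMK (median 1.38) and 6 of 16 with OPH (0.43, 1 fell), and 10 of 16 were lower with OPH than with FMK (median -0.91, 13 with the block). Junb, a subunit of the transcription factor AP-1, rose with FMK (1.57 ± 0.28, adjusted p = 0.00687). Its difference between OPH and FMK (-0.90 ± 0.27) did not pass (adjusted p = 0.0942), but did elsewhere (adjusted p = 4.12e-05 with only the 2 groups in the fit, adjusted p = 0.0197 with the replicate number as a block, adjusted p = 0.000449 with DESeq2, adjusted p = 0.0108 with limma-voom and adjusted p = 3.46e-05 in the libraries numbered 1 and 2). Ereg was lower with OPH (-2.72, adjusted p = 0.000140). Of 6 measured brown fat genes, Ppargc1a, a coactivator of mitochondrial biogenesis, was at 5.10 ± 1.23 CPM with DMSO, 5.41 ± 2.31 with FMK and 30.4 ± 5.44 with OPH (adjusted p = 3.89e-05 for OPH against FMK), and 1 of 6 passed in that comparison (4 with the block).

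The interferon response list rose with both inhibitors. The other scalings moved the list by only -0.10 to 0.11 (lowest median 4.04), too little to test scaling. More macrophages in the treated cultures would have raised their markers, whose higher median was -2.76. The smallest difference within equal replicate numbers was 3.98. Every group holds each number, so this cannot test preparations. A candidate explanation is that the cultures made interferon beta when caspases were inhibited, which was not tested.

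Adipocyte markers had a median of -3.54 with FMK and no call with OPH, and the difference between the inhibitors was called (camera adjusted p = 2.01e-15, adjusted p = 0.145 with an estimated correlation and 0.0409 with that and the replicate block). Its value nearest to 0 within equal replicate numbers, FMK against DMSO, was -1.98. Preparations cannot be tested this way, since every group holds each number. The other scalings moved the list by only -0.10 to 0.11 (highest median -3.54), too little to test scaling. With OPH, which also raised interferon genes, the median was 0.043. Ifnb1 had 80 counts there and 190 with FMK, so this cannot exclude the interferon response. A direct effect of FMK may remain, as may a change in the share of adipocytes, both untested.

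Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 2480, 2249 and 1200 genes for FMK against DMSO, OPH against DMSO and OPH against FMK, and the highest other split gave 0, 0 and 10, so 1, 1 and 1 of 10 splits gave as many. For lists the real split gave 12, 15 and 18 calls and the highest other 10, 15 and 12, so 1, 2 and 1 of 10 gave as many. The split with 15 lists set DMSO replicates 1 and 3 and OPH replicate 3 against the rest and parted 1 replicate number. Among splits parting all 3 numbers the highest other gave 0, 0 and 0 genes and 8, 13 and 12 lists.

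Some genes followed the replicate number in place of the group. Rpsa-ps10 averaged 43.8, 95.7 and 2.16 CPM in the libraries numbered 1, 2 and 3, and Slc7a5, an amino acid transporter gene, averaged 9.95, 37.5 and 49.9 CPM.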
